A study of Mus musculus with 8 samples.

How the data were processed

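Lymph node cells of mice from 2 knockout lines were profiled by single-cell RNA sequencing. Per the labels' protocols, inguinal, axillary and brachial lymph nodes of female littermates were pooled, digested with Collagenase P, Dispase and DNase I and sorted by CD45 into hematopoietic (CD45+) and other (CD45-) cells, and libraries were made with 10x Genomics 3' v3 chemistry. The mice were aged 4 to 6 days (day 5 here), 12 to 15 days (week 2) or 30 to 45 days (week 5). The Aire line carried a knockout of Aire and the TCRb line a knockout of the T cell receptor beta chain locus. Each of the 4 runs (2 lines, 2 fractions) held 6 hashed samples, 1 for each age and genotype, marked with antibody tags.

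The authors deposited whole-number UMI counts per gene and barcode, and tag counts per barcode, with no normalization. Per the file headers, the Aire line runs came from Cell Ranger 3.1.0, with 28692 genes, and the TCRb line runs from Cell Ranger 6.0.0, with 55487 genes. Cell Ranger, Seurat and the mm10 build are named in the submitters' processing notes. The gene tests used the 28125 gene identifiers found in both annotations. Line, run, software version and annotation cannot be separated, so every fit had a term for line and no line was compared with the other by level.

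A barcode was kept with at least 300 genes and at most 10% mitochondrial UMIs, which left 5799 of 7221 barcodes in the Aire line CD45+ run, 9205 of 11340 in the Aire line CD45- run, 42616 of 43182 in the TCRb line CD45+ run and 28550 of 30607 in the TCRb line CD45- run. Tags with at least 1% of a run's tag counts were assigned with Seurat 5.3.0 (HTODemux, quantile 0.99). The deposited notes assign tags to samples by name and sequence. In the TCRb line both matched. In the Aire line the names matched and none of the sequences did, so the ages and genotypes of the Aire line were assigned by tag names alone. By age, fibroblast-like cluster 12 of the Aire line, led by Dlk1, held 212, 4 and 0 cells, and cluster 3 of the TCRb line, with Dlk1 among its leading genes, held 797, 24 and 1. No such check was had for the genotypes of the Aire line. No tag was called in 91 and 447 kept barcodes of the Aire line (CD45+ and CD45-) and in 2295 and 687 of the TCRb line, and these were left out. Of the barcodes with a tag call, doublets made up 11.4% and 12.1% in the Aire line and 34.8% and 22.9% in the TCRb line, and were left out too. Doublets within a sample were estimated from the share of tag doublets among 50 neighbours, and 140, 261, 2383 and 1147 further barcodes were left out in the same order of runs. The clustered singlets numbered 4915, 7436, 23923 and 20347.

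Cells were clustered per run (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 2.0, leidenalg 0.10.2), which gave 27, 36, 35 and 38 clusters. The resolution was raised to this value after a first set of clusters had been viewed. Clusters were named from marker genes fixed before the data were examined, with at least 3 detected markers. The distances used to score the markers were set afterwards. Clusters that met no rule stayed unnamed and held 0.421% to 6.50% of a hashed sample. The names were rebuilt from the counts and may differ from the authors' own.

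UMI counts were summed per hashed sample and class, and a class with fewer than 20 cells in a sample was left out of that sample. This removed the Aire knockout day 5 sample from the blood endothelial-like fit. The sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in an additive model of line, age, Aire knockout and Tcrb knockout, with 6 residual degrees of freedom, or 5 for blood endothelial-like cells. Each age, genotype and line had 1 hashed sample, so the lines and genotypes served as replicates of an age and the ages as replicates of a genotype. The labels do not say how many mice a hashed sample pooled, and p-values of the gene tests measure the spread between these samples. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) are those of the fitted log2 change. In T-like cells the Tcrb contrast was not tested, since the knockout removes most of that class.

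Each of 24 gene lists fixed before the data were examined was tested with camera (limma 3.58.1, correlation 0.01, lists with at least 5 measured members), and again with an estimated correlation. Shares of cells were tested with edgeR on cell counts per class and hashed sample. They were given with exact Clopper-Pearson 95% intervals, which cover counting error only. The p-values of shares rest in part on a dispersion (spread between samples) shared between the classes of a fraction. They can thus be smaller than the spread of a class by itself would give. An exact permutation of the signs of matched pairs was run beside the edgeR tests of shares.

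The rule for named genes, fixed before the data were examined, took per class and contrast the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean log2 CPM of at least 5 and the same direction in every matched pair, up to 4 members of each list by p, and the targeted genes. Genes of the lists for RNA of other cells and for dissociation were given only as lists, except Fos and Hbb-bs, named after their values were seen. The text names a part of these genes, and that part, like the 11 genes given with CPM levels, was chosen after the values were seen. CPM are counts scaled to TMM-adjusted library size, computed here from the deposited counts. Gene positions are from GENCODE vM21 on mm10.

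The tests were run on simulated data first, with 200 genes changed in each simulation. At a 2-fold change, 91.2% of the changed genes were recovered for week 2 against day 5 in fibroblast-like cells (11859 genes) and 80.6% for the Tcrb knockout in the same class (11860 genes). For the Aire and Tcrb knockouts recovery was 53.6% (9162 genes) and 51.7% (9164 genes) in lymphatic endothelial-like and 19.7% (7736 genes) and 55.9% (7727 genes) in blood endothelial-like cells, and 68.3% (9966 genes) for Aire in T-like cells. In blood endothelial-like cells it was 47.5% for week 2 against day 5 (7717 genes). False calls made up 8.43% of calls for week 2 against day 5 in fibroblast-like cells (11859 genes), and over all classes and contrasts from 1.67% for Aire in blood endothelial-like (7736 genes) to 9.09% for Aire in T-like cells (9966 genes), against a threshold of 0.05 for adjusted p. Camera called 1 unchanged list for week 2 against day 5 in fibroblast-like cells (11872 genes), which was not called with an estimated correlation. For the Tcrb knockout in blood endothelial-like cells (7761 genes) it called 1 unchanged list, with an estimated correlation too. Simulated genes were drawn independently of each other. These simulations therefore cannot check camera calls on lists whose genes vary together. For shares, only 1 class per fraction was raised, by 2.83-fold, with no other class lowered. It was called in 50 to 65% of simulations for lymphatic endothelial-like among CD45- cells (8 classes, 4 contrasts) and in 100% for T-like among CD45+ cells. The T-like share so raised exceeds the whole fraction, and the recovery for rarer classes was not simulated. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, another tag rule (at least 10 tag counts, with a share of at least 0.7 in the top tag), doublets kept, wild type samples only, 1 line only, each hashed sample left out in turn and an estimated correlation. The fits of 1 line for the age contrasts, the T-like fit without Tcrb knockout samples and the shares of non-hematopoietic cells were chosen after seeing the data. Python 3.11.15 and R 4.3.3 were used.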

Results

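Lymph node cells were profiled by single-cell RNA sequencing in mice of 3 ages around the first weeks of life, in wild type mice and in 2 knockouts that alter T cells. Aire drives the display of tissue proteins in the thymus, where self-reactive T cells are removed, and the T cell receptor beta chain is needed for alpha beta T cells. The series asks how stromal cells, the non-hematopoietic cells that build the node, respond to waves of T cells around birth. Each line gave a CD45+ and a CD45- run, and each run held 6 hashed samples (wild type, WT, and knockout, KO, at day 5, week 2 and week 5, or D5, W2 and W5). The 24 hashed samples held 49425 cells, 560 to 4433 per sample, with 3872465 to 12558980 UMIs each. Median UMIs per cell ranged from 5239.5 to 12660 in the Aire line and from 1038 to 3285 in the TCRb line. They fell with age in every run and genotype. In wild type they went from 12179.5 at day 5 to 5239.5 at week 5 among Aire line CD45- cells. Among TCRb line CD45+ cells of wild type they went from 1816.5 to 1078. Age thus ran together with depth per cell, and the effect of depth on the age contrasts was not tested.

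The knockout was checked first through Trbc2, a constant gene of the T cell receptor beta chain (chromosome 6, 41546730 to 41548352 of mm10). In CD45+ T-like cells of TCRb line wild type mice, 83.4%, 75.7% and 70.3% of cells had a Trbc2 UMI at day 5, week 2 and week 5. Their median UMIs were 1707, 1365 and 1154, so depth fell beside these shares. In the knockout the shares were 5.17%, 6.18% and 4.79%, beside 4.77%, 5.18% and 3.45% in B-like cells of the same samples. Median UMIs were 1435, 1380.5 and 1144 in these T-like cells and 1694, 1388 and 836 in the B-like cells, so the knockout values lay near the background of free RNA. Trdc, the delta chain constant gene, was seen in 63.8%, 64.3% and 60.9% of knockout T-like cells and in 7.38%, 6.49% and 3.48% of wild type ones. Aire itself (chromosome 10, 78030022 to 78043610) had 0 to 15 UMIs per hashed sample in the Aire knockout and 0 to 19 in the wild type of that line, which checks nothing about the Aire labels.

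Log2 changes below are given ± SE from fits of 12 hashed samples, or 11 for blood endothelial-like cells. Single genes given with a value as rising or falling did so in every matched pair of hashed samples, 4 for age and 3 for blood endothelial-like cells between day 5 and week 2, except where a count of pairs is given. Counts of genes and of list members are by adjusted p alone, with no rule on pairs. Adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

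From day 5 to week 2 fibroblast-like cells raised a matrix protease and lowered imprinted growth and cell division genes. Mmp3, a matrix-degrading protease (chromosome 9, 7445822 to 7455975), rose by 3.31 ± 0.17, adjusted p = 7.80e-08, and averaged 5.56 ± 2.62 CPM at day 5, 55.5 ± 14.7 at week 2 and 497 ± 163 at week 5 (SD, 4 hashed samples). Imprinted growth genes fell, among them Igf2, an insulin-like growth factor (-3.00 ± 0.16, adjusted p = 7.80e-08), Dlk1 (-3.27 ± 0.32) and H19 (-2.77 ± 0.35). Among 14 measured fetal and imprinted growth genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone, camera adjusted p = 3.03e-23). Of the 20 measured cell cycle genes, 0 rose and 19 fell (0 and 20 adjusted over the list alone, camera adjusted p = 3.97e-22), with Top2a, a topoisomerase of dividing cells, at -1.23 ± 0.13. Hmgcs1, an enzyme of cholesterol synthesis, also fell (-2.15 ± 0.16).

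Over the same interval, of 18 measured stromal chemokines and cytokines, 9 rose and 3 fell (10 and 4 adjusted over the list alone, camera adjusted p = 5.80e-04, and adjusted p = 0.194 with an estimated correlation), with the T cell survival factor Il7 at 2.11 ± 0.20, the B cell survival factor Tnfsf13b at 2.81 ± 0.28 and Cxcl12 at 1.77 ± 0.14. Ccl21a, which guides T cells, was at 1.64 ± 0.14, a value that is uncertain because near-identical copies share its reads. Among 18 measured MHC class I presentation genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.64e-08, and adjusted p = 0.149 with an estimated correlation), led by H2-T23 (1.37 ± 0.12). Of the 7 measured MHC class II presentation genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00183, and adjusted p = 0.417 with an estimated correlation). Of 20 measured collagens and matrix members, 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0199, and adjusted p = 0.593 with an estimated correlation). The dissociation list, genes induced by tissue digestion, moved too. Among 15 measured dissociation genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 9.92e-04, and adjusted p = 0.593 with an estimated correlation). In all, 3140 of 12170 genes changed, 1469 up and 1671 down. The cluster with the most fibroblast-like cells differed by age. In the Aire line it was cluster 9, 11 and 4 at day 5, week 2 and week 5, with 46.1%, 26.4% and 43.2% of the class, and in the TCRb line cluster 3, 5 and 2, with 16.4%, 27.8% and 64.9%.

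From week 2 to week 5 fibroblast-like cells raised interferon and antigen presentation genes and lowered dividing-cell and matrix genes. Of the 14 measured type I interferon response genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 8.14e-07, and adjusted p = 0.169 with an estimated correlation), with Rtp4 at 1.54 ± 0.31 and Isg15, a ubiquitin-like interferon product, at 1.18 ± 0.26. Of 18 measured MHC class I presentation genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.38e-16). Among 20 measured interferon-gamma response genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.01e-06, and adjusted p = 0.178 with an estimated correlation). Of the 18 measured stromal chemokines and cytokines, 9 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.26e-08), with Tnfsf13b at 2.29 ± 0.20 and Il6 at 1.44 ± 0.19. Of 14 measured NF-kB and lymphotoxin targets, 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 4.65e-04, and adjusted p = 0.318 with an estimated correlation). Mmp3 rose further (3.15 ± 0.13, adjusted p = 2.33e-09). Lists of lymphocyte genes were called in the same cells. Among 5 measured effector and memory T genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 2.36e-04), and those that rose were Cd44, Id2, S100a4 and S100a6, which stromal cells express too. Of the 9 measured mature B genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0453, and adjusted p = 0.135 with an estimated correlation), and those that rose were Cd69 and H2-Aa, the latter also in the MHC class II list. Of 7 measured germinal centre and plasma genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0375, and adjusted p = 0.135 with an estimated correlation). Among 15 measured hematopoietic RNA members, 1 rose and 0 fell (median 0.26, 0 and 0 adjusted over the list alone, camera adjusted p = 0.41).

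Over the same weeks, of the 20 measured cell cycle genes, 0 rose and 19 fell (0 and 19 adjusted over the list alone, camera adjusted p = 3.66e-35), with Ccnb2 at -3.23 ± 0.27 and Cenpf at -3.06 ± 0.29. Of 20 measured collagens and matrix members, 1 rose and 14 fell (1 and 16 adjusted over the list alone, camera adjusted p = 7.24e-11, and adjusted p = 0.135 with an estimated correlation), among them the elastic fibre genes Eln (-0.86 ± 0.085) and Fbn2 (-1.96 ± 0.13). Imprinted genes kept falling. Among 14 measured fetal and imprinted growth genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 7.24e-11). The dissociation list moved in full. Of the 15 measured dissociation genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.23e-12, and adjusted p = 0.135 with an estimated correlation). The counts were 1241 genes up and 1126 down of 12170.

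**Figure D1:**
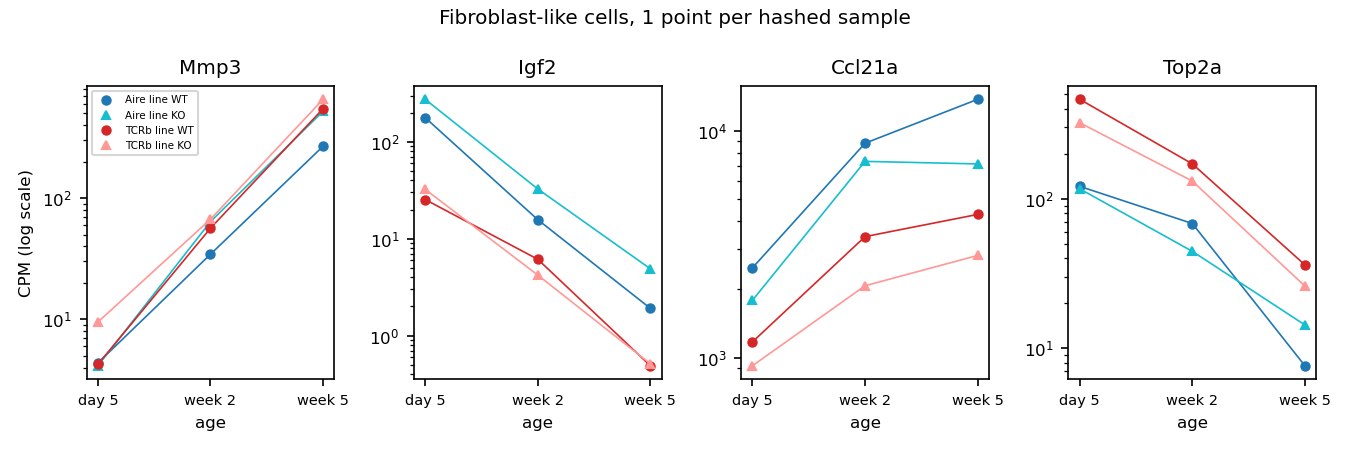
CPM (log axis) of Mmp3, Igf2, Ccl21a and Top2a in fibroblast-like cells, 1 point per hashed sample, by age, line and genotype. Mmp3 averaged 5.56 CPM at day 5 and 497 CPM at week 5, and Igf2 went from 128 to 1.95 CPM.

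Lymphatic endothelial-like cells also lowered imprinted growth and cell division genes between day 5 and week 2. Cyp51, an enzyme of cholesterol synthesis, fell (-1.99 ± 0.17, adjusted p = 6.64e-07), as did Hmgcs1 (-1.68 ± 0.18) and H19 (-1.93 ± 0.13). Of 11 measured fetal and imprinted growth genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 1.27e-12). Among 20 measured cell cycle genes, 0 rose and 10 fell (0 and 16 adjusted over the list alone, camera adjusted p = 6.06e-15). Ackr4, a receptor that takes up chemokines, rose (0.87 ± 0.13). Out of 15 measured dissociation genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.54e-26). Of 5 measured erythroid RNA members, 1 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00165, and adjusted p = 0.359 with an estimated correlation). The counts were 253 up and 275 down of 9493 genes, a total of 528. With 1 hashed sample left out, for lymphatic endothelial-like cells: genes changed, week 2 against day 5, the count was 280 without Aire WT W2, 196 without TCRb WT D5, 294 without TCRb KO D5, 264 without TCRb WT W2 and 287 without TCRb KO W2. In the Aire line cluster 15 held 66.3% and 53.7% of the class at day 5 and week 2, and cluster 5 held 79.2% at week 5. In the TCRb line clusters 13 and 6 held 49.9% and 49.6% at day 5, cluster 6 held 62.8% at week 2 and cluster 17 held 64.1% at week 5.

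Between week 2 and week 5 the interferon genes rose in lymphatic endothelial-like cells. Ifi27l2a, an interferon-induced gene (chromosome 12, 103442167 to 103443680), rose by 3.78 ± 0.30, adjusted p = 6.32e-08, and averaged 226 ± 168 CPM at day 5, 204 ± 77.5 at week 2 and 2610 ± 334 at week 5 (SD, 4 hashed samples). All measured members of the type I interferon list passed. Among 15 measured type I interferon response genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 3.81e-25), with Ifit1 at 2.55 ± 0.23 and Irf7 at 2.32 ± 0.33. Of the 19 measured interferon-gamma response genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 2.17e-05, and adjusted p = 0.377 with an estimated correlation). Of 18 measured MHC class I presentation genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.28e-07, and adjusted p = 0.224 with an estimated correlation). Igf2 fell (-4.55 ± 0.36), as did Madcam1, an adhesion ligand of lymphocytes (-1.74 ± 0.17), while the lymphatic genes Ackr4 (1.13 ± 0.13) and Mmrn1 (1.01 ± 0.12) rose. Among 20 measured cell cycle genes, 0 rose and 18 fell (0 and 18 adjusted over the list alone, camera adjusted p = 6.24e-18). Of the 11 measured fetal and imprinted growth genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 3.09e-08). Of 15 measured dissociation genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 6.24e-18). Among 5 measured naive T genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0098, and adjusted p = 0.0859 with an estimated correlation). The counts were 741 up and 649 down.

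Blood endothelial-like cells raised Hspb1, a heat shock protein (2.02 ± 0.18, adjusted p = 2.79e-06), and Cxcl12 (1.25 ± 0.16) between day 5 and week 2, and lowered Madcam1 (-1.72 ± 0.32) and Mest (-1.97 ± 0.38). Among 15 measured dissociation genes, 13 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 5.19e-25, and adjusted p = 0.139 with an estimated correlation). Of 20 measured cell cycle genes, 0 rose and 7 fell (0 and 14 adjusted over the list alone, camera adjusted p = 1.18e-09, and adjusted p = 0.327 with an estimated correlation). Among 19 measured interferon-gamma response genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00252, and adjusted p = 0.344 with an estimated correlation). High endothelial adhesion genes mark vessels that admit lymphocytes. Of the 13 measured high endothelial adhesion genes, 1 rose and 2 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0404, and adjusted p = 0.337 with an estimated correlation). The counts were 314 up and 304 down of 8098 genes, a total of 618. With 1 hashed sample left out, for blood endothelial-like cells: genes changed, week 2 against day 5, the count was 56 without TCRb WT D5, 150 without TCRb KO D5, 198 without TCRb WT W2 and 283 without TCRb KO W2. In the TCRb line, cluster 22, led by Glycam1, held 47.4% and cluster 4 held 39.7% of the class at day 5, and cluster 4 held 63.5% and 81.6% at week 2 and week 5. Cluster 7 held the whole class in the Aire line.

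From week 2 to week 5 Madcam1 fell further in blood endothelial-like cells (-4.61 ± 0.49, adjusted p = 1.41e-05), with 837 ± 566 CPM at day 5, 218 ± 207 at week 2 and 10.9 ± 11.2 at week 5 (SD, 3 hashed samples at day 5 and 4 later). Glycam1, a ligand for lymphocyte entry, rose (2.15 ± 0.48, adjusted p = 0.0109), by an amount that differed between the lines (-2.65 ± 0.38, TCRb minus Aire line). Of 15 measured type I interferon response genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 6.93e-23, and adjusted p = 0.0685 with an estimated correlation), with Ifit3 at 2.42 ± 0.39 and Irf7 at 2.19 ± 0.30. Among 18 measured MHC class I presentation genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 6.99e-16, and adjusted p = 0.0685 with an estimated correlation). Of the 20 measured cell cycle genes, 0 rose and 11 fell (0 and 14 adjusted over the list alone, camera adjusted p = 1.82e-22, and adjusted p = 0.0685 with an estimated correlation). Of the 15 measured dissociation genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 4.56e-30, and adjusted p = 0.0685 with an estimated correlation). In all, 436 genes (281 up, 155 down) changed. With 1 sample left out, for blood endothelial-like cells: genes changed, week 5 against week 2, the count was 253 without TCRb WT W2, 199 without TCRb KO W2, 257 without TCRb WT W5 and 201 without TCRb KO W5.

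**Figure D2:**
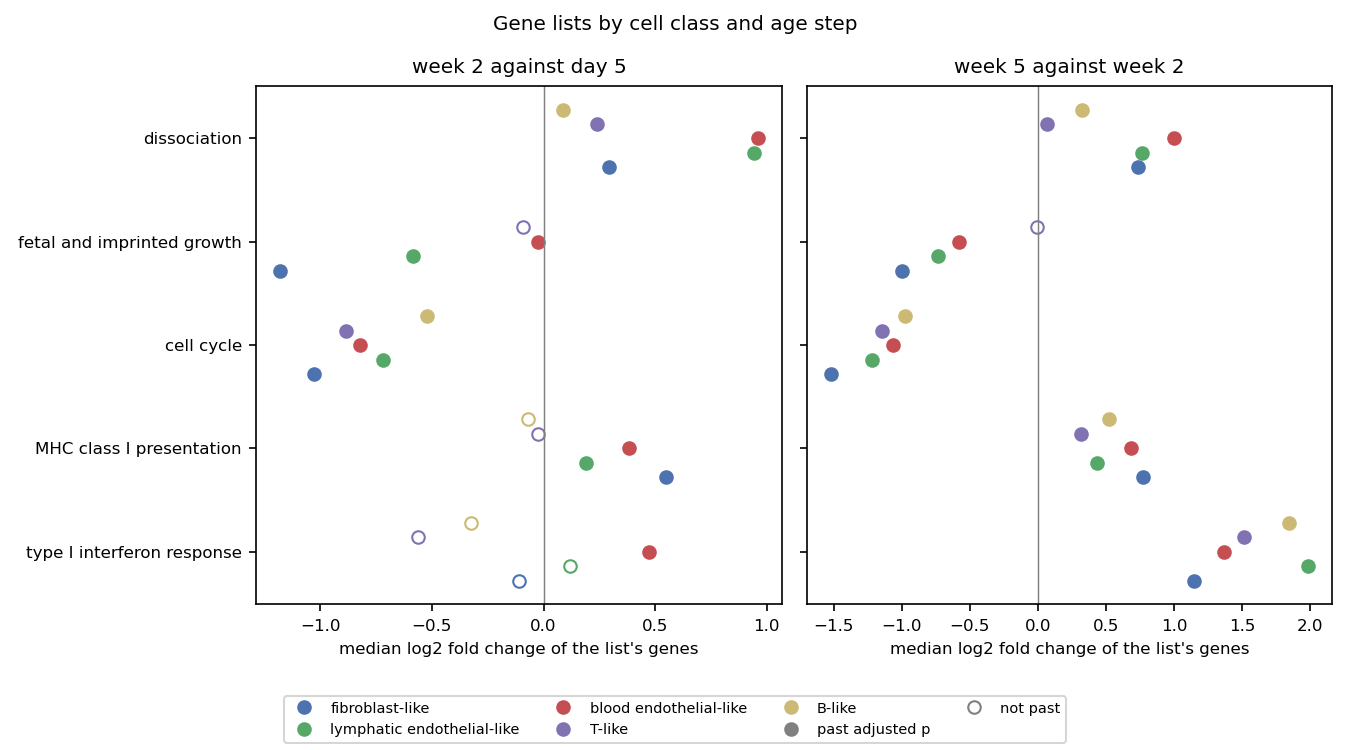
Median log2 change of 5 gene lists (horizontal axis) in the 5 classes, for both steps of age, with filled points for lists past the camera adjusted p and open points for the others. The type I interferon list rose between week 2 and week 5 in all 5 classes, with medians from 1.15 in fibroblast-like to 1.99 in lymphatic endothelial-like cells, and with an estimated correlation the adjusted p was 0.0413 in lymphatic endothelial-like, 0.169 in fibroblast-like, 0.0685 in blood endothelial-like, 0.0562 in T-like and 0.0687 in B-like cells.

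Between day 5 and week 2 T-like cells raised Klf2 and S1pr1. Klf2, a factor that keeps T cells in circulation (chromosome 8, 72319033 to 72321656), rose by 0.89 ± 0.095, adjusted p = 1.76e-04, and S1pr1 (0.50 ± 0.11) rose with it. Among 9 measured naive T genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 1.11e-05, and adjusted p = 0.311 with an estimated correlation). Of the 20 measured cell cycle genes, 0 rose and 18 fell (0 and 20 adjusted over the list alone, camera adjusted p = 4.44e-17, and adjusted p = 0.311 with an estimated correlation), with Ccnb2 at -1.29 ± 0.22. Of 9 measured regulatory T genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0457, and adjusted p = 0.544 with an estimated correlation), with Foxp3 at 0.96 ± 0.25 in 3 of 4 pairs. Among 20 measured interferon-gamma response genes, 0 rose and 5 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.00307, and adjusted p = 0.424 with an estimated correlation). Out of 15 measured dissociation genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00734, and adjusted p = 0.544 with an estimated correlation). B cell precursor genes moved too. Of 9 measured immature B genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 3.57e-07, and adjusted p = 0.258 with an estimated correlation). In all, 1055 genes of 10497 (336 up, 719 down) changed. With 1 sample left out, for T-like cells: genes changed, week 2 against day 5, the count was 595 without Aire WT D5, 469 without Aire KO D5, 374 without Aire WT W2, 238 without Aire KO W2, 653 without TCRb WT D5 and 409 without TCRb WT W2. It was 8 in the TCRb line alone, where the knockout leaves mostly Trdc-bearing cells in the class. The cluster with the most T-like cells in the Aire line was 1, 1 and 2 by age, with 26.2%, 33.9% and 32.7% of the class. In the TCRb line it was cluster 0, with 30.2%, 31.7% and 30.3% over both genotypes, but that cluster held 14 of 566 T-like cells of the knockout at week 2 and 32 of 731 at week 5.

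From week 2 to week 5 interferon genes rose in T-like cells. Among 15 measured type I interferon response genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 5.80e-26, and adjusted p = 0.0562 with an estimated correlation). Ifit3 was at 2.69 ± 0.44 and Isg15 at 1.20 ± 0.24. Of the 18 measured MHC class I presentation genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 3.48e-18). Lists of B cell genes were called in the same cells. Of 13 measured mature B genes, 2 rose and 0 fell (median 0.46, 8 and 0 adjusted over the list alone, camera adjusted p = 9.23e-07, and adjusted p = 0.0562 with an estimated correlation), with Cd69, which T cells express too, among those that rose. Among 9 measured immature B genes, 0 rose and 2 fell (median -0.21, 0 and 4 adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.289 with an estimated correlation). Gzma, a granzyme of cytotoxic cells (chromosome 13, 113093825 to 113100981), fell (-3.02 ± 0.60, adjusted p = 0.0102). Of the 9 measured regulatory T genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone, camera adjusted p = 1.36e-04, and adjusted p = 0.112 with an estimated correlation), with Il2ra at -0.90 ± 0.15. Of 20 measured cell cycle genes, 0 rose and 13 fell (0 and 20 adjusted over the list alone, camera adjusted p = 1.02e-29, and adjusted p = 0.0562 with an estimated correlation). Of 15 measured dissociation genes, 1 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00886, and adjusted p = 0.441 with an estimated correlation). In all, 323 genes (182 up, 141 down) changed. With 1 sample left out, for T-like cells: genes changed, week 5 against week 2, the count was 563 without Aire KO D5, 117 without Aire WT W2, 149 without Aire KO W2, 170 without Aire WT W5, 122 without Aire KO W5, 138 without TCRb WT W2, 101 without TCRb KO W2 and 213 without TCRb WT W5, and 20 in the TCRb line alone.

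B-like cells raised genes of mature B cells and of antigen presentation at each step of age. Between day 5 and week 2, of the 13 measured mature B genes, 7 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 8.32e-08, and adjusted p = 0.115 with an estimated correlation). Of 8 measured MHC class II presentation genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 7.38e-08, and adjusted p = 0.115 with an estimated correlation), with Ciita, its main activator, at 0.81 ± 0.15. Chd3 (1.87 ± 0.22, adjusted p = 1.80e-06) and Abcg1, a cholesterol exporter (1.58 ± 0.18), rose. Among 20 measured cell cycle genes, 0 rose and 9 fell (0 and 12 adjusted over the list alone, camera adjusted p = 7.23e-07, and adjusted p = 0.382 with an estimated correlation). Among 15 measured dissociation genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 3.76e-04, and adjusted p = 0.115 with an estimated correlation). Of 9 measured naive T genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 3.76e-04, and adjusted p = 0.115 with an estimated correlation). Among 16 measured hematopoietic RNA members, 3 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.0456, and adjusted p = 0.132 with an estimated correlation). In all, 692 genes of 9181 (316 up, 376 down) changed. With 1 sample left out, for B-like cells: genes changed, week 2 against day 5, the count was 276 without Aire KO D5, 302 without Aire WT W2, 226 without Aire KO W2, 281 without TCRb WT D5, 342 without TCRb KO D5 and 347 without TCRb WT W2. The cluster with the most B-like cells by age was 3, 6 and 0 in the Aire line (66.2%, 27.4% and 49.9% of the class) and 1, 1 and 2 in the TCRb line (43.9%, 38.2% and 43.9%).

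From week 2 to week 5, of the 13 measured mature B genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.36e-24), with the complement receptor Cr2 at 1.48 ± 0.15 and Ighd, the IgD heavy chain, at 0.98 ± 0.097. Of 8 measured MHC class II presentation genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 2.69e-22). Among 14 measured type I interferon response genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 3.67e-26, and adjusted p = 0.0687 with an estimated correlation), with Ifit3 at 2.93 ± 0.45. S100a6 (-2.62 ± 0.29, adjusted p = 1.47e-07), Bhlhe41 (-1.87 ± 0.17) and Arid3a (-1.52 ± 0.17) fell in B-like cells. Of the 20 measured cell cycle genes, 0 rose and 12 fell (0 and 14 adjusted over the list alone, camera adjusted p = 1.43e-10, and adjusted p = 0.174 with an estimated correlation). Of the 15 measured dissociation genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00262, and adjusted p = 0.133 with an estimated correlation). Among 9 measured naive T genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 1.28e-04, and adjusted p = 0.0779 with an estimated correlation). In all, 744 genes (384 up, 360 down) changed. With 1 sample left out, for B-like cells: genes changed, week 5 against week 2, the count was 426 without TCRb WT W2, 380 without TCRb KO W2 and 459 without TCRb KO W5.

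No single gene passed for the Aire knockout in stromal or T-like cells, while camera called several gene lists. In simulated data, 2-fold changes for this knockout were recovered for 82.5% of changed genes in fibroblast-like cells (11891 genes) but for 19.7% in blood endothelial-like cells (7736 genes). In fibroblast-like cells, of the 20 measured interferon-gamma response genes, none passed alone (median 0.35, 0 and 0 adjusted over the list alone, camera adjusted p = 4.16e-07, and adjusted p = 0.479 with an estimated correlation), with Gbp2 at 0.77 ± 0.26, adjusted p = 0.873. In B-like cells, of 18 measured MHC class I presentation genes, none passed alone (median 0.30, 11 and 0 adjusted over the list alone, camera adjusted p = 1.92e-15, and adjusted p = 0.22 with an estimated correlation). In T-like cells, among 20 measured interferon-gamma response genes, none passed alone (median 0.33, 4 and 0 adjusted over the list alone, camera adjusted p = 2.89e-09, and adjusted p = 0.155 with an estimated correlation). In blood endothelial-like cells, of the 18 measured collagens and matrix members, none passed alone (median -1.35, 0 and 10 adjusted over the list alone, camera adjusted p = 1.13e-18), with Col1a1 at -1.89 ± 0.37, adjusted p = 0.146 in 2 of 2 pairs. Fibroblast markers outside that list moved by a median of -0.96 in the same cells. Of 5 measured erythroid RNA members, none passed alone (median -1.41, 0 and 2 adjusted over the list alone, camera adjusted p = 7.88e-05, and adjusted p = 0.206 with an estimated correlation). Among 5 measured effector and memory T genes, none passed alone (median -0.67, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0418, and adjusted p = 0.182 with an estimated correlation). Of the 20 measured cell cycle genes, none passed alone (median 0.73, 7 and 0 adjusted over the list alone, camera adjusted p = 1.39e-16, and adjusted p = 0.182 with an estimated correlation). Dissociation lists were also called in T-like and B-like cells. In T-like cells, out of 15 measured dissociation genes, none passed alone (median -0.19, 0 and 1 adjusted over the list alone, camera adjusted p = 3.66e-06, and adjusted p = 0.332 with an estimated correlation). In B-like cells, of 15 measured dissociation genes, 0 rose and 1 fell (median -0.17, 0 and 1 adjusted over the list alone, camera adjusted p = 2.32e-04, and adjusted p = 0.22 with an estimated correlation).

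By edgeR the Aire knockout count was 0 in fibroblast-like (576 at unadjusted p under 0.05, 5 by DESeq2), lymphatic endothelial-like (416, 1 by DESeq2), blood endothelial-like (408, 0 by DESeq2) and T-like cells (307, 0 by DESeq2). In the same order the counts were 22, 1, 43 and 0 in the Aire line alone and 125, 28, 52 and 36 with no filter on low counts, and in B-like cells 24 and 17, from 1. With 1 hashed sample left out, for lymphatic endothelial-like cells: genes changed, Aire knockout against wild type, the count was 2 without Aire KO D5, 1 without Aire KO W2, 3 without Aire WT W5, 1 without Aire KO W5 and 1 without TCRb WT W5. For blood endothelial-like cells: genes changed, Aire knockout against wild type, the count was 7 without Aire WT D5, 1 without Aire WT W2, 8 without Aire KO W2, 1 without Aire WT W5, 2 without Aire KO W5 and 2 without TCRb KO D5. For T-like cells: genes changed, Aire knockout against wild type, the count was 1 without Aire WT D5, 1 without Aire WT W2, 2 without Aire KO W2, 1 without Aire WT W5 and 5 without Aire KO W5. In B-like cells Fos, an immediate early gene of the dissociation list, was the gene that passed (-0.71 ± 0.11, adjusted p = 0.00288), named after its value was seen. For B-like cells: genes changed, Aire knockout against wild type, the count was 0 without Aire WT D5, 0 without Aire KO D5, 2 without Aire WT W2, 5 without Aire KO W2, 5 without Aire KO W5, 3 without TCRb KO D5 and 2 without TCRb WT W5. The genotypes of the Aire line rest on tag names, since the tag sequences did not match.

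The Tcrb knockout changed the cell makeup of the CD45+ fraction. T-like cells fell from 50.5% to 19.5% of CD45+ cells (-1.38 ± 0.26, adjusted p = 1.90e-05), NK and ILC-like cells rose from 3.80% to 11.2% (1.66 ± 0.30, adjusted p = 1.90e-05), and dendritic-like cells rose from 6.86% to 18.4% (1.47 ± 0.29, adjusted p = 4.07e-05). T-like cells fell among CD45- cells too, from 0.80% to 0.29% (-1.29 ± 0.30, adjusted p = 0.0204). They were few there, with 9, 29 and 19 cells in the wild type and 6, 11 and 7 in the knockout by age. The sort should deplete that fraction of them. Each of these shares moved the same way in 3 of 3 pairs. Exact permutation of the pair signs (two-sided) cannot go below 0.25 with 3 pairs. The adjusted p of shares, here and below, rests in part on a dispersion shared between classes. Shares in a fraction sum to its whole, so a fall of 1 class raises the others, and both depend on the CD45 sort.

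**Figure D3:**
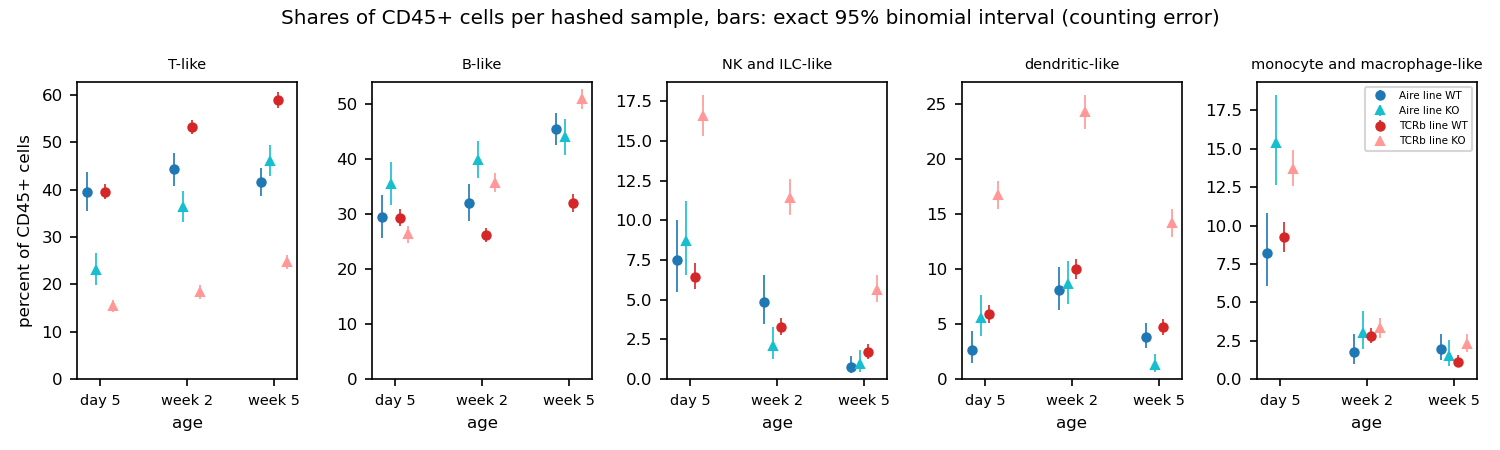
Percent of CD45+ cells in 5 classes per hashed sample, with exact 95% intervals as bars, by age, line and genotype. T-like cells averaged 19.5% in the Tcrb knockout and 50.5% in its wild type.

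In stroma the Tcrb knockout moved lists but no gene past the threshold. In fibroblast-like cells, of the 20 measured cell cycle genes, none passed alone (median -0.47, 0 and 9 adjusted over the list alone, camera adjusted p = 4.03e-12, and adjusted p = 0.345 with an estimated correlation), with Cdk1 at -0.58 ± 0.13, adjusted p = 0.215 and Mcm5 at -0.58 ± 0.15. Of 14 measured NF-kB and lymphotoxin targets, none passed alone (median 0.19, 1 and 0 adjusted over the list alone, camera adjusted p = 8.02e-04, and adjusted p = 0.751 with an estimated correlation). Among 15 measured dissociation genes, none passed alone (median 0.39, 10 and 0 adjusted over the list alone, camera adjusted p = 1.52e-14, and adjusted p = 0.345 with an estimated correlation). In lymphatic endothelial-like cells, of the 20 measured cell cycle genes, none passed alone (median -0.39, 0 and 0 adjusted over the list alone, camera adjusted p = 4.93e-06, and adjusted p = 0.433 with an estimated correlation). Of the 15 measured dissociation genes, none passed alone (median 0.07, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0469, and adjusted p = 0.433 with an estimated correlation). Among 5 measured erythroid RNA members, none passed alone (median -0.34, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00739, and adjusted p = 0.433 with an estimated correlation). In blood endothelial-like cells, of the 13 measured high endothelial adhesion genes, none passed alone (median 0.58, 2 and 0 adjusted over the list alone, camera adjusted p = 4.16e-06, and adjusted p = 0.169 with an estimated correlation). Out of 15 measured dissociation genes, none passed alone (median 0.41, 0 and 0 adjusted over the list alone, camera adjusted p = 6.23e-09, and adjusted p = 0.206 with an estimated correlation). Among 5 measured effector and memory T genes, none passed alone (median -0.61, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0221, and adjusted p = 0.169 with an estimated correlation).

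By edgeR the Tcrb knockout count was 0 in fibroblast-like (839 at unadjusted p under 0.05, 17 by DESeq2), lymphatic endothelial-like (385, 0 by DESeq2) and blood endothelial-like cells (317, 0 by DESeq2). With no filter on low counts it was 217, 6 and 20 in the same order, and in the TCRb line alone 202, 25 and 10. For fibroblast-like cells: genes changed, Tcrb knockout against wild type, the count was 1 without Aire KO D5, 3 without TCRb WT W2, 1 without TCRb KO W2 and 2 without TCRb KO W5. For blood endothelial-like cells: genes changed, Tcrb knockout against wild type, the count was 3 without TCRb WT W2 and 2 without TCRb KO W5. In the TCRb line alone, a fit with fewer residual degrees of freedom, 202 of 12040 genes changed in fibroblast-like cells (110 up, 92 down). Of these, 201 were tested in the fit of 12 samples, all in the same direction there. That fit takes the Tcrb effect from the same TCRb line samples, so the shared direction is no separate support. Examples chosen after their values were seen were the chemokine Ccl2 (0.83 ± 0.093), Il6 (0.81 ± 0.13) and Ptgs2, which makes prostaglandins (0.98 ± 0.11), which rose, and Stmn2 (-2.06 ± 0.20) and Birc5, of cell division (-0.70 ± 0.15), which fell. Stmn2 is a leading gene of fibroblast-like cluster 19, which held 158 of 1688 wild type and 68 of 1925 knockout cells of the class at week 2, and 49 of 831 and 18 of 943 at week 5. Among the 202 were 9 dissociation and 9 cell cycle members, from lists of 15 and 20 measured genes, beside 202 of 12040 genes in all. A difference in dissociation between the samples cannot be told apart from the knockout here.

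In B-like cells 4 genes passed for the Tcrb knockout. Ggct, an enzyme of glutathione breakdown, rose (1.43 ± 0.20, in 3 of 3 pairs), and Suclg1, of the citric acid cycle, fell (-0.68 ± 0.13, adjusted p = 0.0168). Hbb-bs, a hemoglobin gene (3.07 ± 0.51), rested on the TCRb knockout week 5 sample at 457.9 CPM and was -0.15 without it. Igkv5-43, an immunoglobulin light chain segment (-2.92 ± 0.51), rested on the TCRb wild type week 5 sample at 232 CPM. Both were named after their values were seen. For B-like cells: genes changed, Tcrb knockout against wild type, the count was 1 without TCRb WT W5, and 1 by DESeq2.

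Cell makeup also changed with age. Among CD45+ cells, monocyte and macrophage-like cells fell from 11.6% ± 3.46 at day 5 to 2.73% ± 0.684 at week 2 (SD, 4 hashed samples; -2.02 ± 0.26, adjusted p = 3.29e-08). Neutrophil-like (-1.21 ± 0.32, adjusted p = 0.00211), NK and ILC-like (-0.98 ± 0.28, adjusted p = 0.00272) and mast and basophil-like cells (-1.57 ± 0.43, adjusted p = 0.00211) fell too, as did fibroblast-like cells in this fraction (-0.82 ± 0.30, adjusted p = 0.0126), and dendritic-like cells rose (0.81 ± 0.28, adjusted p = 0.00932). All 4 pairs moved alike. From week 2 to week 5 dendritic-like (-1.23 ± 0.27, adjusted p = 4.83e-04), neutrophil-like (-1.73 ± 0.42, adjusted p = 4.83e-04) and NK and ILC-like cells (-1.25 ± 0.30, adjusted p = 4.83e-04) fell in 4 of 4 pairs. Mast and basophil-like cells (-1.89 ± 0.62, adjusted p = 0.00695) fell in 4 of 4 pairs too. In the Aire line these were falls from 1 cell (wild type) and 2 cells (knockout) to 0. In the TCRb line they were falls from 13 to 5 cells (wild type) and from 22 to 4 (knockout). Monocyte and macrophage-like (-0.71 ± 0.29, adjusted p = 0.0255) and fibroblast-like cells (-1.16 ± 0.34, adjusted p = 0.0036) fell in 3 of 4. Exact permutation of pair signs cannot go below 0.125 with 4 pairs.

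Among CD45- cells, pericyte and smooth muscle-like cells, which wrap vessels, fell from 7.83% ± 2.93 at week 2 to 2.70% ± 1.47 at week 5 (-1.61 ± 0.38, adjusted p = 0.0209). T-like (1.47 ± 0.25, adjusted p = 0.00212) and B-like cells (2.66 ± 0.81, adjusted p = 0.0398) rose between day 5 and week 2 in this fraction, which the sort should deplete of them. Each of these moved the same way in 4 of 4 pairs. At week 2 T-like and B-like cells made up 22.5% and 18.3% of CD45- cells in Aire line wild type. They made up 1.03% and 3.45% in TCRb line wild type. At week 5 they made up 27.1% and 28.0% in Aire line wild type. For the Aire knockout the smallest adjusted p of a share was 0.736 among CD45+ and 0.78 among CD45- cells. For CD45-negative cells: shares of cell classes, the number of calls was 2 without Aire KO W5, 2 without Aire WT W5, 1 without TCRb KO W2, 1 without TCRb KO W5, 2 without TCRb WT W2, 2 without TCRb WT W5, from 4 in all.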

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

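Tests chosen after the result was seen were those of the change of hematopoietic RNA, of the rise that other cells' RNA would give and of dissociation for the interferon list, that of the size of the fall of endothelial matrix genes and those of other splits of the samples, except the split test of the TCRb line alone.

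The change with age differed between the lines, by an interaction test, for 199 genes in fibroblast-like cells between day 5 and week 2 (82 larger and 117 smaller in the TCRb line) and 22 between week 2 and week 5. The counts were 6 and 18 in lymphatic endothelial-like, 6 and 19 in blood endothelial-like and 36 and 61 in B-like cells, and 2 in T-like cells for the first step. In simulated data, 2-fold differences between the lines at the first and second step were recovered for 52.3% and 32.6% of changed genes in fibroblast-like, 17.6% and 11.8% in lymphatic endothelial-like, 0% and 5.64% in blood endothelial-like, 22.7% and 21.8% in T-like and 37.2% and 34.4% in B-like cells. False calls made up 11.1% and 5.97% of calls in fibroblast-like, 19% and 14.8% in lymphatic endothelial-like, 18.5% and 16.3% in T-like and 2.67% and 8.22% in B-like cells, and 15.4% at the second step in blood endothelial-like cells. Line also stands for run, software version and annotation. Col11a1 in fibroblast-like cells (2.68 ± 0.28), Iigp1 in lymphatic endothelial-like cells (2.65 ± 0.30), Glycam1 in blood endothelial-like cells (-2.65 ± 0.38), Cd74 in T-like cells (1.36 ± 0.18) and S100a6 in B-like cells (2.44 ± 0.18) were among them, chosen after their values were seen. The Tcrb effect exceeded the Aire effect for 1 gene, Ggct in B-like cells (1.70 ± 0.28).

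Differences of share effects, on the log2 scale, were 2.51 for blood endothelial-like cells among CD45- cells (week 5 against week 2, TCRb minus Aire line), and, for the Tcrb minus the Aire knockout among CD45+ cells, 1.51 for dendritic-like, 1.89 for NK and ILC-like and -1.08 for T-like cells.

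Of 100 groups of 4 hashed samples, 4 had a sample far from the others, and chance gives about 1 in 20. Dendritic-like cells were 24.26% of CD45+ cells in the TCRb knockout at week 2. Mmp3 in fibroblast-like cells was 9.486 CPM in the TCRb knockout at day 5, Gzma in T-like cells 332.8 CPM in the Aire knockout at day 5, and S100a6 in B-like cells 211.4 CPM, the lowest, in Aire wild type at day 5.

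A tag that the deposited notes do not list marked 3404 CD45+ and 3792 CD45- cells of the TCRb line. The CD45+ cells were 31.9% NK and ILC-like, 21.9% monocyte and macrophage-like and 6.84% T-like, and the CD45- cells were 68.3% fibroblast-like and 11.3% pericyte and smooth muscle-like. These cells were in no comparison.

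The type I interferon list rose between week 2 and week 5 in all 5 classes, with the call lost with an estimated correlation in fibroblast-like (adjusted p = 0.169), blood endothelial-like (adjusted p = 0.0685), T-like (adjusted p = 0.0562) and B-like cells (adjusted p = 0.0687). RNA of T-like, B-like and endothelial cells would give at most 0.07465 of the level in fibroblast-like cells at week 5 and 0.172 of the rise, which argues against it as the source of that level and as the whole cause of the rise there, while a part in the rise (the hematopoietic RNA list moved by a median of 0.259 beside 1.148) and its role in the other 4 classes cannot be told apart. Inside 1 cluster per run the list rose by at least 0.5 of its rise over the class in 5 of 5 classes. The lowest ratio of a single pair was 0.481, in B-like cells, and blood endothelial-like cells had 2 pairs, both of the TCRb line. In fibroblast-like cells the clusters held 98 of 804 cells at week 5 in the Aire line and 67 of 1774 in the TCRb line. A shift between clusters cannot be told apart there. In the other 4 classes it is argued against as the whole cause, for the clusters tested. The T-like pair of the Tcrb knockout was not tested, with 14 cells of its cluster at week 2. From week 2 to week 5 clusters led by Ifit1 or Ifit3 grew. In the Aire line they went from 4.50% to 10.35% of T-like and from 2.67% to 8.46% of B-like cells. In the TCRb line these shares went from 0.855% to 2.345% and from 0.664% to 5.249%. A part of such shifts in the rise cannot be told apart. Dissociation is argued against as the whole cause in T-like cells, where its list moved by 0.064 and the interferon list by 1.512. By pair these lists ran from -0.157 to 0.538 and from 0.438 to 2.215, so a part there cannot be told apart. Dissociation may also contribute in the 3 stromal classes, where the lowest dissociation median was 0.736. Age stays open as the biological explanation, untested.

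The cell cycle list was lower in Tcrb knockout fibroblast-like cells, with adjusted p = 0.345 with an estimated correlation. Inside the cluster with the most cells of both genotypes it moved by 0.1484 over day 5 and week 2, with no list gene to measure at week 5. This test is void, since clusters are themselves formed on cell cycle genes. A cluster led by cell cycle genes held 8.4% of wild type and 4.8% of knockout cells of the class at day 5. The shares were 3.3% and 1.8% at week 2 and 0.12% and 0.11% at week 5. Cluster 14, led by the histone genes Hist1h2ap and H1f5, was not counted there and was not split by genotype. It held 10.35%, 2.69% and 0.28% of the class at day 5, week 2 and week 5. A shift between clusters cannot be told apart. Dissociation cannot be told apart either, with a rank correlation of -0.5 over 3 ages. The real split gave -0.4678, as low or lower in 1 of 10 splits, and the lowest other was -0.4281, with splits too few for a share under 0.05. The knockout stays open, untested.

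The collagen and matrix list was lower in Aire knockout blood endothelial-like cells. Fibroblast RNA carried in these cells may account for it, since fibroblast markers outside the list moved by a median of -0.961, with 4 of 8 measured and Dcn lowest (-2.56 ± 0.54). A fall of endothelium's own matrix genes as large as that of the list (-1.351) is argued against, since Col4a1, Col4a2, Sparc and Lama4 lay no lower than -0.6535 at 2 SE below their values. Their median was -0.1674, and the SEs of the single genes had a median of 0.191, so a smaller fall in these cells cannot be told apart. The knockout stays open, untested, and none of these single genes passed.

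Other splits of the same samples gave as many genes as the age contrasts in 1 of 35 splits each, the real one. These splits ignore the matching of samples by line and genotype. Each of the others also leaves part of the real age difference in its residual, so the splits do not exclude chance. Splits that keep the matched pairs are too few for a share under 0.05. The highest other counts for week 2 against day 5 and week 5 against week 2 were 1 and 4 in fibroblast-like (real 3140 and 2367), 8 and 6 in lymphatic endothelial-like (528 and 1390), 25 and 95 in blood endothelial-like (618 and 436), 203 and 5 in T-like (1055 and 323) and 258 and 170 in B-like cells (692 and 744). Each knockout contrast has 10 splits, too few for a share under 0.05. Real and highest other counts for Aire were 0 and 10 in fibroblast-like, 0 and 54 in lymphatic endothelial-like, 0 and 1 in T-like and 1 and 55 in B-like cells. For Tcrb they were 0 and 3, 0 and 3, 0 and 1 and 4 and 7 in fibroblast-like, lymphatic endothelial-like, blood endothelial-like and B-like cells, and 202 and 2 in fibroblast-like cells of the TCRb line alone. As many genes came from 10 splits in each contrast with a real count of 0, from 6 for Aire and 4 for Tcrb in B-like cells and from 1 for the TCRb line alone. The splits with 54 and 55 genes, many times the real counts, point to a structure of the samples, and which one was not tested.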

How the results depend on the processing

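The fits of 1 line for the age contrasts, the T-like fit without Tcrb knockout samples and the shares of non-hematopoietic cells were chosen after seeing the data. With RLE factors all 19 counts stayed within 1.5 times and all 293 named genes kept their call. The T-like fit without Tcrb knockout samples kept both counts within that range. Of the named genes, 263 kept their call with DESeq2 (19 lost, 2 gained), 266 with no filter (27 gained), 272 with the other tag rule (20 lost) and 276 with doublets kept (14 lost). Calls of named genes lost and kept were 46 and 204 in the TCRb line only and 40 and 212 in the Aire line only. They were 36 and 213 in wild type samples only, and 134 and 3313 over all fits with 1 hashed sample left out. Among share calls, 14 held with the other tag rule and 5 were lost, and 19 held with doublets kept. The cause was not tested for these changes and those below, except that fits of fewer samples hold fewer degrees of freedom.

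With other settings, results that moved by over 1.5 times gave these values. Counts of fibroblast-like cells: genes changed, week 2 against day 5, were 1267 in wild type samples only. Counts of fibroblast-like cells: genes changed, week 5 against week 2, were 950 in wild type samples only and 1262 in the Aire line only. Counts of fibroblast-like cells: genes changed, Aire knockout against wild type, were 5 with DESeq2, 125 with no filter on low counts and 22 in samples of the knockout's own line only. Counts of fibroblast-like cells: genes changed, Tcrb knockout against wild type, were 17 with DESeq2, 217 with no filter on low counts, 202 in samples of the knockout's own line only and 0 to 3 with 1 hashed sample left out. Counts of lymphatic endothelial-like cells: genes changed, week 2 against day 5, were 250 with DESeq2, 198 in wild type samples only, 91 in the Aire line only and 196 to 593 with 1 hashed sample left out. Counts of lymphatic endothelial-like cells: genes changed, week 5 against week 2, were 782 with DESeq2, 317 in wild type samples only and 458 in the Aire line only. Counts of lymphatic endothelial-like cells: genes changed, Aire knockout against wild type, were 1 with DESeq2, 28 with no filter on low counts, 1 with doublets kept, 1 in samples of the knockout's own line only and 0 to 3 with 1 hashed sample left out. Counts of lymphatic endothelial-like cells: genes changed, Tcrb knockout against wild type, were 6 with no filter on low counts, 7 with the other tag rule and 25 in samples of the knockout's own line only. Counts of blood endothelial-like cells: genes changed, week 2 against day 5, were 338 with DESeq2, 83 in wild type samples only, 106 in the Aire line only and 56 to 796 with 1 hashed sample left out. Counts of blood endothelial-like cells: genes changed, week 5 against week 2, were 232 with DESeq2, 87 in wild type samples only, 181 in the Aire line only and 199 to 536 with 1 hashed sample left out. Counts of blood endothelial-like cells: genes changed, Aire knockout against wild type, were 52 with no filter on low counts, 43 in samples of the knockout's own line only and 0 to 8 with 1 hashed sample left out. Counts of blood endothelial-like cells: genes changed, Tcrb knockout against wild type, were 20 with no filter on low counts, 10 in samples of the knockout's own line only and 0 to 3 with 1 hashed sample left out. Counts of T-like cells: genes changed, week 2 against day 5, were 675 with DESeq2, 8 in the TCRb line only and 238 to 1344 with 1 hashed sample left out. Counts of T-like cells: genes changed, week 5 against week 2, were 213 with DESeq2, 663 with no filter on low counts, 20 in the TCRb line only, 169 in the Aire line only and 101 to 563 with 1 hashed sample left out. Counts of T-like cells: genes changed, Aire knockout against wild type, were 36 with no filter on low counts, 1 with the other tag rule and 0 to 5 with 1 hashed sample left out. Counts of B-like cells: genes changed, week 2 against day 5, were 311 with DESeq2, 99 in wild type samples only and 226 to 785 with 1 hashed sample left out. Counts of B-like cells: genes changed, week 5 against week 2, were 353 with DESeq2, 204 in wild type samples only, 1169 in the TCRb line only, 314 in the Aire line only and 380 to 826 with 1 hashed sample left out. Counts of B-like cells: genes changed, Aire knockout against wild type, were 17 with no filter on low counts, 2 with the other tag rule, 24 in samples of the knockout's own line only and 0 to 5 with 1 hashed sample left out. Counts of B-like cells: genes changed, Tcrb knockout against wild type, were 1 with DESeq2, 10 with no filter on low counts, 19 with doublets kept, 18 in samples of the knockout's own line only and 1 to 5 with 1 hashed sample left out. Lists called with an estimated correlation numbered 7 in fibroblast-like, 7 in lymphatic endothelial-like, 1 in blood endothelial-like, 1 in T-like and 2 in B-like cells. Among shares, 1 call in CD45- cells held with non-hematopoietic cells as the whole. By exact permutation of signs 0 and 0 held in both fractions, since it cannot reach the threshold.

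Mki67 in B-like cells, week 5 against week 2 reversed to 0.634 in the Aire line only. Cxcl9 in blood endothelial-like cells, week 2 against day 5 reversed to -0.728 with the other tag rule. Cxcl9 in blood endothelial-like cells, week 2 against day 5 reversed to -0.973 with doublets kept. Cenpf in blood endothelial-like cells, Aire knockout against wild type reversed to -0.254 with doublets kept. Ube2c in blood endothelial-like cells, Aire knockout against wild type reversed to -1.118 with doublets kept.

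A lone remaining sample of its kind is assumed to vary like the others where 1 hashed sample was left out. For CD45-negative cells: shares of cell classes, calls then ranged from 1 to 6. Hbb-bs in B-like cells, Tcrb knockout against wild type, ranged from -0.15 to 3.968. Medians of lists whose tested direction turned in the absence of 1 sample ranged as follows. The list dissociation in blood endothelial-like cells, Aire knockout against wild type went from -0.013 to 0.422. Across samples, the list type I interferon response in blood endothelial-like cells, Aire knockout against wild type went from -0.173 to 0.681. The list cell cycle in blood endothelial-like cells, Tcrb knockout against wild type went from -0.48 to 0.051. Across samples, the list NF-kB and lymphotoxin targets in fibroblast-like cells, Aire knockout against wild type went from -0.275 to -0.014. The list collagens and matrix in fibroblast-like cells, Aire knockout against wild type went from 0.039 to 0.218. Across samples, the list immature B in T-like cells, week 5 against week 2 went from -1.25 to -0.035. The list cell cycle in T-like cells, Aire knockout against wild type went from -0.518 to 0.18.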

Other observations

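Further lists that were fixed in advance were called by camera. Which of them are given here was chosen after their values were seen. In B-like cells between week 2 and week 5, of the 18 measured MHC class I presentation genes, 11 rose and 0 fell (median 0.52, 11 and 0 adjusted over the list alone, camera adjusted p = 2.17e-20, and adjusted p = 0.0708 with an estimated correlation). In T-like cells over the same step, of 8 measured MHC class II presentation genes, 2 rose and 0 fell (median 0.53, 6 and 0 adjusted over the list alone, camera adjusted p = 2.01e-07, and adjusted p = 0.0562 with an estimated correlation). The mature B list moved beside them by a median of 0.46. Among 9 measured naive T genes, 2 rose and 0 fell (median 0.34, 6 and 0 adjusted over the list alone, camera adjusted p = 2.55e-06, and adjusted p = 0.112 with an estimated correlation). In blood endothelial-like cells over that step, of the 19 measured interferon-gamma response genes, 6 rose and 0 fell (median 0.78, 12 and 0 adjusted over the list alone, camera adjusted p = 1.27e-08, and adjusted p = 0.136 with an estimated correlation). In fibroblast-like cells over that step, of 7 measured MHC class II presentation genes, 3 rose and 0 fell (median 0.68, 5 and 0 adjusted over the list alone, camera adjusted p = 2.64e-04, and adjusted p = 0.135 with an estimated correlation). In lymphatic endothelial-like cells between day 5 and week 2, among 5 measured MHC class II presentation genes, 2 rose and 0 fell (median 1.53, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0021, and adjusted p = 0.26 with an estimated correlation), beside the dissociation list, whose median was 0.94.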
